A study of Mus musculus with 19 samples.

How the data were processed

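RNA from 19 libraries of mouse embryonic stem cells and their descendants was measured by sequencing of stranded mRNA libraries. Each library comes with 1 table of genes, and 2 columns of it were used, the reads per gene and the RPKM. The counts are whole numbers of uniquely mapped reads per gene, made by the authors with the program rpkmforgenes on a RefSeq gene table, per the file headers. The RPKM values (reads scaled by exon length and library size) were computed by the authors from those counts with 3' untranslated regions left out of the gene models, per the file headers. Reads were converted with bcl2fastq and CASAVA 1.8.2, trimmed with Trimmomatic 0.3.3 and aligned to mouse genome build mm9 with TopHat2 2.0.14 and Bowtie2 2.2.5, per the submitters' processing notes. The counts were checked to be whole numbers in every table.

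The tables hold 22756 gene entries under 22479 distinct names. Overlapping genes are joined under 974 double names, and 448 entries share their name with another entry. Entries that share a name hold 0.31 to 0.67% of a library's reads, and each was kept as its own entry. Reads in genes ranged from 5771671 to 14233421 per library, and 14796 to 16990 genes had reads. Rn45s, a ribosomal RNA precursor, took 0.27 to 1.66% of the reads. A count of 0 was given a floor of 3 reads over the group, the 95% upper limit of a zero count. Ratios that rest on 1 to 3 reads are given with a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

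The samples were grouped by their labels into 9 groups. The file headers name 2 sequencing projects: 17 libraries belong to the first, and AICAR GFP-positive replicates 1 and 2 form the second. The grouping, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Agreement of replicates was checked with a chi-square per degree of freedom for 32 pairs of libraries of a group, which ranged from 1.96 to 51.05, where 1 is counting noise alone. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples.

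Groups with at least 1 replicated side were compared by the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3). It used TMM scaling, the tool's expression filter (a minimum count of 10 and a total of 15) and Benjamini-Hochberg adjusted p under 0.05. Only the libraries compared entered each fit. CPM are read counts scaled to the library size and by these factors within a comparison, so a group's mean differs slightly between comparisons. Where 1 side has a single library, the test assumes that the lone sample varies like the other group. Power was tested on simulated data with changes of 2- and 4-fold in 100 genes each. All genes of a comparison were given the same spread, the common value of its fit. Genes that vary more are recovered less often, so the recoveries do not hold for every gene. Comparisons of 1 library with 1 library have no p-value. They use log2 ratios of CPM with a prior count of 2, and each list's median was ranked among 10000 random lists matched for size and for expression in 20 bins.

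The 27 gene lists were naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, primitive and visceral endoderm, cardiac muscle, mesenchyme and extracellular matrix, smooth muscle, neural, trophoblast, endothelial and blood, skin and simple epithelium, 2-cell-like, germline, imprinted, DNA methylation enzymes, MEK-ERK response, Wnt response, LIF-STAT3 response, AMPK pathway, glycolysis, oxidative phosphorylation, purine synthesis, sterol and fatty acid synthesis, p53 targets, cell cycle G2-M and stress response. Dnmt3a and Dnmt3b stand in both the epiblast and the DNA methylation list. Lists were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, repeated with an estimated correlation, and with fry. Their p were adjusted over the lists of a comparison. With an estimated correlation, camera takes its p from the residual degrees of freedom of the fit. These were 2 for AICAR GFP-positive cells against each single library and 3 for sorted lines against AICAR GFP-positive cells. A list can hardly pass there, so a lost call does not show that the list stayed unchanged.

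The rule for named genes takes, per tested comparison, the 10 largest positive and the 10 largest negative log2 fold changes. They come from genes with adjusted p under 0.05, a mean of at least 2 log2 CPM in the higher group and every library of one group above every library of the other. Of each list described, the 2 to 4 members with the smallest adjusted p are added. Comparisons of 1 library with 1 take the 8 largest and 8 smallest ratios among genes with at least 100 reads in 1 library, and list members with at least 50 reads. Zfp42, Pou5f1, Nanog, Sox2, Klf4, Esrrb, Fgf5 and T are named in every group. Predicted genes without a proper name, mitochondrial and ribosomal RNA genes were passed over.

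The alternatives were DESeq2 1.42.0, median-of-ratios factors, no expression filter, limma on log2 of RPKM plus 1, 1 fit of all 19 libraries, both kinds of line as 1 group, a replicate block, and each replicate left out in turn. Colony lines were left out in turn only against AICAR GFP-positive cells. Against sorted lines and undifferentiated cells, colony line 7 was the only colony line left out singly. Added after the data were seen were the first sequencing project only and the fits without colony line 7 and without colony lines 4 and 5. A fit with replicate number as a block was run only for sorted lines against AICAR GFP-positive cells, since the other groups share too few numbers. Genes were placed on chromosomes with assembly GRCm38.p6, which is not the build the reads were aligned to, so only chromosome names and gene order were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.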

Results

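Gene expression was measured in 19 libraries of mouse embryonic stem (ES) cells that carry a destabilised green fluorescent protein (GFP) reporter at Rex1 (Zfp42), a gene of the naive ES cell state. The cells were differentiated in serum medium. After 2 days, cells negative for GFP and for SSEA1, a surface antigen of undifferentiated mouse ES cells, were sorted and kept in differentiation medium to day 15 with or without AICAR. AICAR is a nucleoside that cells convert into an AMP mimic, which activates the energy-sensing kinase AMPK. The groups hold 1 library each of undifferentiated cells, day-2 cells, day-2 SSEA1-negative GFP-negative cells, day-15 cells without AICAR, unfractionated AICAR cells and AICAR GFP-negative cells. They also hold 3 libraries of AICAR GFP-positive cells, 8 of lines grown from picked GFP-positive colonies (colony lines) and 2 of lines grown from sorted GFP-positive cells (sorted lines). Both kinds of line were expanded with LIF and inhibitors of MEK and GSK3, the medium that holds ES cells in the naive state. Sample titles and the sorting field of the labels differ for the first day-2 library and the AICAR fractions, and the titles were followed. Reads in genes were 5771671 to 8262357 in 17 libraries and 12751260 and 14233421 in AICAR GFP-positive replicates 1 and 2, which alone form a second sequencing project.

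Zfp42, the reporter locus, stood at 449 CPM (read counts scaled to library size) in undifferentiated cells, 27.9 at day 2, 21 in the day-2 sorted cells and 4.92 at day 15 without AICAR. With AICAR it stood at 215 CPM in unfractionated cells, 55.6 in GFP-negative cells and 547 ± 114 (SD, n = 3) in GFP-positive cells. It was 563 ± 84.5 in colony lines (SD, n = 8) and 506 ± 2.51 in sorted lines (SD, n = 2). Pou5f1 (Oct4), a central pluripotency factor, was still at 1420 CPM at day 2 against 1630 in undifferentiated cells, and was at 23.9 CPM at day 15. It was 556 CPM in unfractionated AICAR cells, 559 in GFP-negative and 1210 ± 170 in GFP-positive cells, 1560 ± 68.7 in colony and 1620 ± 13.5 in sorted lines. Nanog, a naive-state transcription factor, was 564 CPM in undifferentiated cells, 61 at day 2, 45.8 in the day-2 sorted cells, 3.51 at day 15, 105 in unfractionated AICAR cells, 33.7 in GFP-negative and 225 ± 33.3 in GFP-positive cells. It was 515 ± 42.4 in colony lines and 545 ± 12.6 in sorted lines. Esrrb, another naive factor, went from 338 CPM in undifferentiated cells to 11.4 at day 2, 8.17 in the day-2 sorted cells and 2.93 at day 15. It was 123 CPM in unfractionated AICAR cells, 70.8 in GFP-negative, 326 ± 69.6 in GFP-positive cells, 388 ± 27.9 in colony and 369 ± 25.1 in sorted lines. Sox2, the partner factor of Pou5f1, was 338, 97.5, 66.4 and 13.3 CPM in undifferentiated, day-2, day-2 sorted and day-15 cells. It was 262 CPM in unfractionated AICAR cells, 252 in GFP-negative, 526 ± 74.6 in GFP-positive cells, 317 ± 29.9 in colony and 301 ± 1.44 in sorted lines.

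Klf4, a naive factor also expressed in differentiated epithelia, was 234 CPM in undifferentiated cells, 10.3 at day 2, 15.8 in the day-2 sorted cells and 140 at day 15. It was 242 CPM in unfractionated AICAR cells, 492 in GFP-negative cells, 290 ± 29.5 in GFP-positive cells, 153 ± 16.7 in colony and 153 ± 4.08 in sorted lines. Fgf5, a marker of the epiblast after implantation, was 0.152 CPM in undifferentiated cells (1 read), 43.2 at day 2, 41.3 in the day-2 sorted cells and 2.34 at day 15. It was 5.38 CPM in unfractionated AICAR cells, 19.8 in GFP-negative cells and 11.8 ± 0.674 in GFP-positive cells, against 0.455 ± 0.42 in colony and 0.301 ± 0.425 in sorted lines. T (Brachyury), a primitive streak factor, was 1.37 CPM in undifferentiated cells, 0.389 at day 2, 0.584 in the day-2 sorted cells, 11.2 at day 15, 0.689 in unfractionated AICAR cells, 2.22 in GFP-negative, 0.636 ± 0.662 in GFP-positive cells, 2.8 ± 0.699 in colony and 1.44 ± 0.119 in sorted lines.

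**Figure D1:**
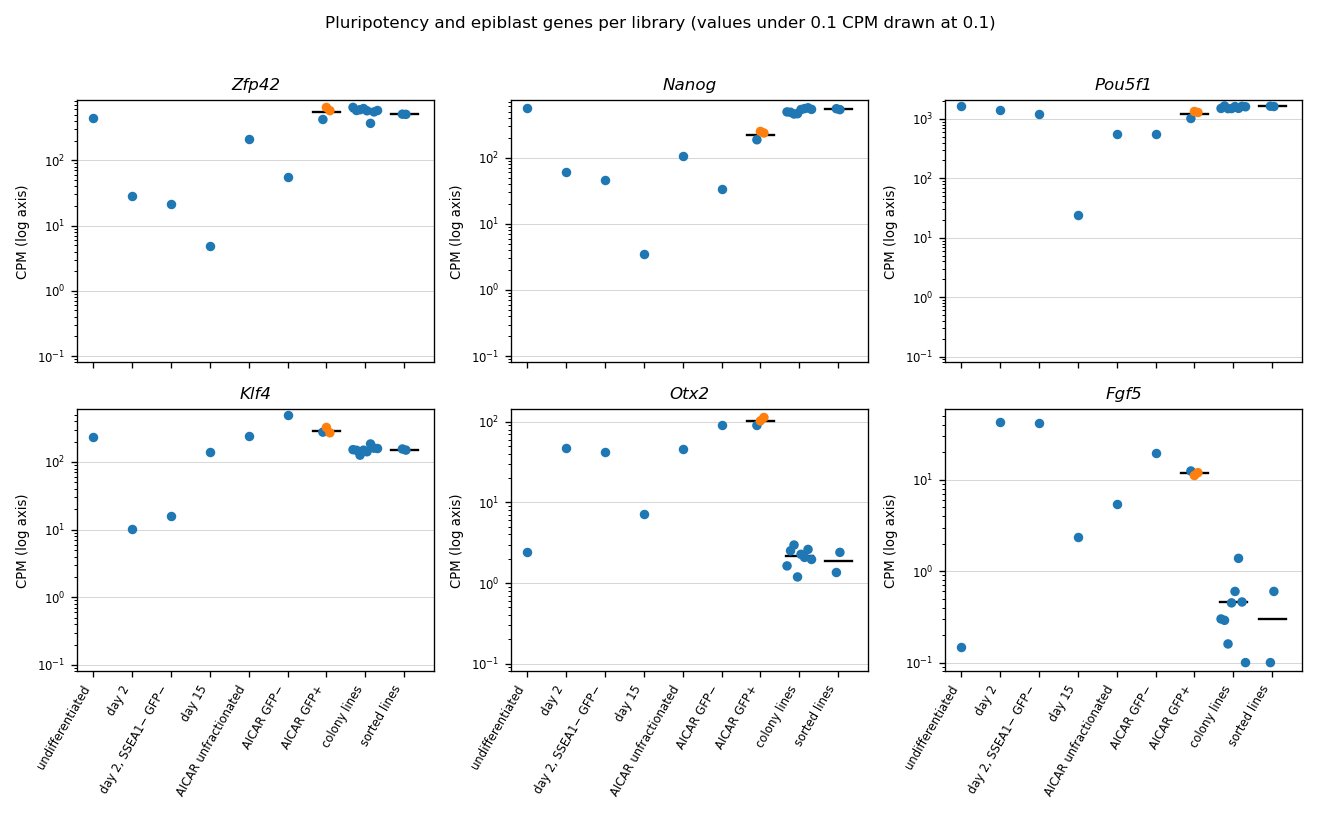
CPM per library on a log axis for Zfp42, Nanog, Pou5f1, Klf4, Otx2 and Fgf5 in the 9 groups, with 1 point per library (blue, first sequencing project; orange, second), a black line at the mean of each replicated group, and values under 0.1 CPM drawn at 0.1. Zfp42 is 4.92 CPM at day 15 without AICAR and averages 547 CPM in AICAR GFP-positive cells, while Otx2 is 90.01 to 113.05 CPM in these cells and 1.19 to 2.96 CPM in the colony and sorted lines.

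Day-2 cells were compared with undifferentiated cells to show the first step out of the naive state. Of 17 naive pluripotency genes with enough reads, 16 were more than 2-fold lower at day 2 and 0 were higher. Among them Prdm14, a repressor of differentiation signals, was 0.13 against 45.7 CPM, and Tfcp2l1, a factor of self-renewal, 1.43 against 109. Of 15 formative and primed epiblast genes, which mark cells after implantation, 10 were higher and 1 lower, with Pou3f1 at 149 against 0.455 CPM and Otx2 at 47.3 against 2.43. General pluripotency genes split, with 5 of 18 higher and 2 lower: Utf1 was 457 against 137 CPM and Sox2 97.5 against 338. The DNA methyltransferases Dnmt3b (1910 against 141 CPM) and Dnmt3a (582 against 55.3) were the highest members of a methylation list with 3 of 9 genes higher and 1 lower. LIF-STAT3 response genes, which read the self-renewal signal of LIF, had 0 of 10 higher and 7 lower. The list medians lay at percentile 0 (naive), 100 (epiblast), 100 (methylation) and 0 (LIF-STAT3) of random lists. Single libraries give no replicate check and no p-value here or in the other comparisons of 1 library with 1. Of 8174 genes with at least 100 reads, 629 were more than 2-fold higher at day 2 and 677 lower. The largest ratios were those of Car4 (98.9 against 0.152 CPM), Pou3f1, Sema6a (53.6 CPM against 0 reads), Zfp608, Wt1, Fgf5, Enpp2 and Cthrc1. The smallest were those of Trpm1 (0.26 against 65.6), Slc15a1 (0 reads against 31 CPM), Prdm14, Cdx1 (0.13 against 44.5), Jam2 (1.3 against 176), Mras, Ntn1 and Tcl1 (0 reads, at least 57.3-fold lower).

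The day-2 SSEA1-negative GFP-negative cells, the starting cells of the AICAR culture, were compared with undifferentiated cells in the same way. The naive genes were again 16 of 17 lower, and 9 of 15 epiblast genes were higher and 1 lower. The 2-cell-like genes, which are normally active in the early embryo and in a rare ES cell state, were higher in 8 of 8, with Zscan4f at 711 against 78.2 CPM and Zscan4c at 686 against 76. Zscan4 copies are near-identical, so reads cannot be assigned to 1 copy with certainty. Of the LIF-STAT3 genes, 7 of 10 were lower, with Bcl3 at 0.584 against 53.1 CPM and Socs3, the feedback inhibitor of the pathway, at 1.9 against 29.4. Smooth muscle genes had 7 of 9 higher. Cpt1a, the enzyme of mitochondrial fatty acid import in the AMPK pathway list, was 12.7 against 136 CPM and the autophagy kinase Ulk1 37.9 against 216, but the list as a whole did not shift, with 4 of 23 genes lower and 1 higher (percentile 65.9). Among 7992 genes, 632 were more than 2-fold higher and 712 lower. Genes with the largest ratios were Sema6a, Car4, Pou3f1, Zfp608, Mmp25, Fgf5, Wt1 and Kif1a (84.6 against 0.607 CPM). Those with the smallest were Jam2 (0.438 against 176), Cdx1, Trpm1, Mras, Porcn, Notum (0.438 against 58.4, a secreted Wnt inhibitor), Prdm14 and Khdc3.

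The day-2 SSEA1-negative GFP-negative library and the other day-2 library were compared to show what the sort selected. The labels differ on whether the other day-2 library was sorted too, and if it was, the comparison does not show the effect of the sort. Of 7793 genes, 22 were more than 2-fold higher in the sorted cells and 2 lower, with 0 beyond 8-fold either way. The 2-cell-like list had 3 of 8 genes higher (percentile 100), with Zscan4b at 350 against 170 CPM and Zscan4e at 405 against 197. No naive gene of 13 passed 2-fold, although their median lay at percentile 0 of random lists, with Nr0b1 at 3.79 against 6.88 CPM and Klf4 at 15.8 against 10.3. Cubn, an endoderm receptor, was 2.19 against 6.62 CPM. Other genes with the largest ratios were Tdpoz3 (19.8 against 8.57), Arg2 and Tsix with Xist (144 against 68.2), and lower were Spp1 (6.13 against 13.1) and H19+Mir675 (30.8 against 61.5).

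Day-15 cells without AICAR were compared with undifferentiated and with day-2 SSEA1-negative GFP-negative cells to show where differentiation led. All 24 mesenchyme and matrix genes were more than 2-fold above the undifferentiated library. The fibrillar collagens Col1a1 and Col3a1 stood at 13300 against 3.34 and 9550 against 1.67 CPM. All 12 smooth muscle, all 17 endoderm, 13 of 15 cardiac and 10 of 11 epithelial genes were also higher, with Krt5, a keratin of stratified epithelium, at 663 CPM against 0 reads. Naive genes were lower in 16 of 17 and general pluripotency genes in 15 of 17, with Nanog at 3.51 against 564 CPM. Lower too were 24 of 30 oxidative phosphorylation genes, 9 of 16 purine synthesis genes, such as Gart at 109 against 564 CPM, and 12 of 19 G2-M genes, such as Ccnb1 at 102 against 387. Imprinted genes were higher in 20 of 26. Percentiles were 100 for the mesenchyme, smooth muscle, endoderm, epithelial and imprinted lists and 78.7 for the cardiac list, which random lists often reach. They were 0.1 or less for the naive, general pluripotency, oxidative phosphorylation and purine lists. Random lists were matched on the mean of the same 2 libraries, so those for genes with a low mean hold large ratios themselves. The streak list, with a median log2 ratio of 4.16, lay at percentile 53.4. The cardiac percentile therefore cannot tell whether the rise of that list (median 4.23) is ordinary. Of 9790 genes, 2815 were more than 2-fold higher and 2306 lower. They were led by Col6a1, Col3a1, Col6a3, Tnc, Col1a1, Krt5, Igf2 (counted with Igf2as) and Col1a2 and at the other end by Gdf3, Lefty2 (1.4 against 296 CPM), Cdx1, Calcoco2, Nanog and Aurkc. Against the day-2 sorted cells, all 18 general pluripotency genes and 12 of 15 epiblast genes were lower, with Utf1 at 5.15 against 406 CPM and Dnmt3b at 44 against 1790. Higher were all 17 endoderm genes (Col4a2 7750 against 10.1 CPM), all 24 mesenchyme genes and all 12 smooth muscle genes (Acta2, smooth muscle actin, 1820 against 8.76). The imprinted growth regulator Dlk1 was 858 against 8.17 CPM. Against the same cells 8 of 29 oxidative phosphorylation genes were lower and 1 higher (percentile 7.7). Lower there were also 6 of 19 G2-M genes (percentile 10.3) and 12 of 16 purine synthesis genes (percentile 0). Among 9758 genes 2702 were higher and 2061 lower.

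Unfractionated AICAR cells were compared with day-15 cells without AICAR to show the effect of the compound on the whole culture. Naive genes were more than 2-fold higher in 13 of 16 and lower in 0, with Tdh, a threonine enzyme of ES cells, at 336 against 6.09 CPM, Zfp42 at 215 against 4.92 and Esrrb at 123 against 2.93. General pluripotency genes were higher in 15 of 17 and epiblast genes in 8 of 13, with Utf1 at 178 against 5.15 CPM and Nodal at 43.2 against 1.76. Mesenchyme genes were lower in 18 of 24, cardiac in 11 of 15, epithelial in 7 of 11 and imprinted genes in 18 of 26. Among these, the matrix proteoglycan genes Lum and Dcn were at 0 reads against 285 CPM (at least 690-fold lower) and 4.55 against 468. Col3a1 stood at 300 against 9550, Hand2 at 2.62 against 61.9, Krt5 at 0.138 against 663 and Dlk1 at 6.48 against 858. Endoderm genes split, 4 of 18 higher and 6 lower: Amn and Cubn, which form an uptake receptor of visceral endoderm, were 67.7 against 1.05 and 660 against 50.7 CPM, and Afp, a fetal serum protein, 2.76 against 28.6. Glycolysis genes were lower in 10 of 21, with Bnip3 at 14.5 against 171 CPM. Of 25 AMPK pathway genes 2 were higher and 1 lower, with the deacetylase Sirt1 at 145 against 26.8 CPM. Percentiles were 100 for the naive, general pluripotency and epiblast lists, 0 for the mesenchyme, cardiac, epithelial, imprinted and glycolysis lists and 74.3 for the AMPK list. Of 9607 genes, 938 were higher and 1463 lower. Cyp2b23 (40.4 CPM against 0 reads), Tcf15 (54.6 against 0.702) and Zfp600 (485 against 9.6) were among the largest ratios and Eln (0.276 against 197) and Krt4 (0 reads against 184 CPM) among the smallest.

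AICAR GFP-negative cells, compared with day-15 cells without AICAR, show the part of the AICAR culture labelled as negative for the reporter protein. RNA of Zfp42, the reporter locus, was still at 55.6 against 4.92 CPM. Naive genes were higher in 11 of 13 (Tdh 243 against 6.09 CPM, Dppa5a 220 against 9.13) and general pluripotency genes in 17 of 18. Epiblast genes were higher in 11 of 14 and lower in 1 (Otx2 91.3 against 7.14, Dnmt3b 579 against 44, Lefty2 48.3 against 1.4). Endoderm genes were higher in 9 of 18 and lower in 5, with Amn at 24.9 against 1.05 CPM and Apob, a lipoprotein gene, at 4.27 against 48.1. Mesenchyme genes were lower in 22 of 24 and higher in 2, smooth muscle lower in 11 of 12, cardiac in 13 of 15, epithelial in 9 of 11 and imprinted in 19 of 27. Col3a1 was 26.6 against 9550 CPM, the smooth muscle genes Tagln and Actg2 38.3 against 806 and 9.5 against 350, and the keratin Krt14 0.475 against 348. In the AMPK list, 4 of 25 were higher and 1 lower, with Prkaa2, a catalytic subunit of AMPK itself, at 61.9 against 15.7 CPM. Percentiles were 100 for the naive, general pluripotency, epiblast and endoderm lists and 0.4 or less for the mesenchyme, smooth muscle, cardiac, epithelial and imprinted lists, and 38.3 for the AMPK list. Of 9493 genes, 1096 were higher and 1813 lower. Cyp2b23, Fam71a (19.2 CPM against 0 reads), Tcf15 and Gpat2 were among the largest ratios and Krt15 (0 reads against 215 CPM), Krt1, Lum, Krt4, Ogn and Col15a1 among the smallest.

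**Figure D2:**
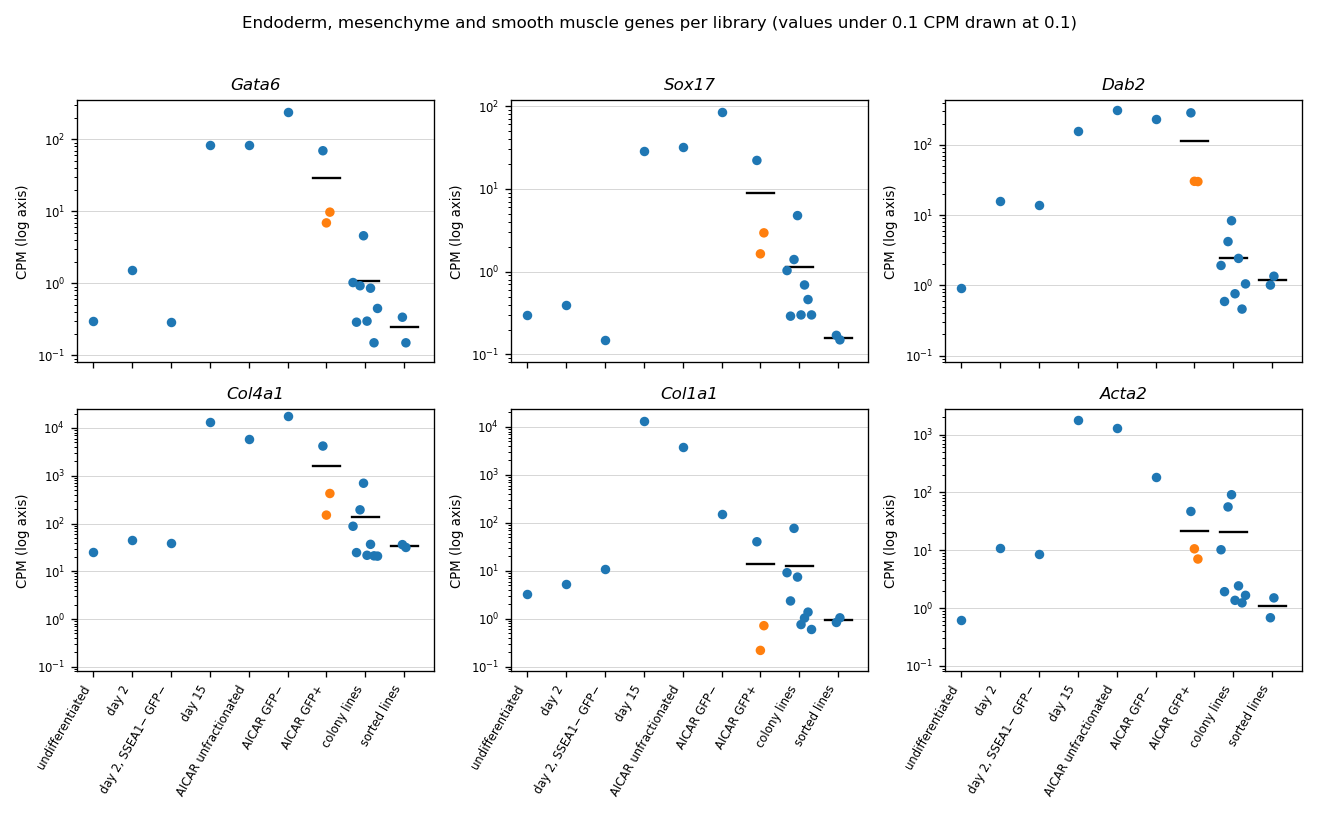
CPM per library on a log axis for the endoderm genes Gata6, Sox17, Dab2 and Col4a1, the collagen gene Col1a1 and smooth muscle actin Acta2 in the 9 groups, with 1 point per library (blue, first sequencing project; orange, second), a black line at the mean of each replicated group, and values under 0.1 CPM drawn at 0.1. Among AICAR GFP-positive cells, Gata6 is 69.74 CPM in replicate 3 and 6.94 and 9.79 CPM in replicates 1 and 2, against 240.61 CPM in the GFP-negative library, and in colony line 5 Col4a1 is 697.39 CPM.

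AICAR GFP-positive cells, the cells that expressed the reporter at day 15, were tested against day-15 cells without AICAR. Pluripotency genes rose and most mesenchyme and muscle genes fell. Of 18 naive genes 16 rose and 0 fell, with Zfp42 at 597 ± 126 (SD, n = 3) against 5.23 CPM (log2 fold change 6.83 ± 0.43 SE, adjusted p = 0.00212). Nanog stood at 246 ± 37.7 against 3.73 (6.04 ± 0.34, adjusted p = 0.00178). General pluripotency genes rose in 16 of 18 and fell in 0: Pou5f1 by 5.70 ± 0.32 (adjusted p = 0.00183) and L1td1, an RNA-binding protein of ES cells, by 5.73 ± 0.29 (adjusted p = 0.00169). Epiblast genes rose in 10 of 16 and fell in 1, with Otx2 up by 3.87 ± 0.26 (adjusted p = 0.00237). Among germline genes 9 of 17 rose and 0 fell, such as the RNA-binding protein Dazl at 59.8 against 0.498 CPM (adjusted p = 0.00366). Mesenchyme genes fell in 21 of 24, smooth muscle genes in 12 of 12, cardiac genes in 13 of 17 and imprinted genes in 20 of 28, with 1 imprinted gene up. Col5a1 was 18.7 against 2390 CPM (log2 -7.00 ± 0.24, adjusted p = 0.00165) and the muscle filament gene Des 4 against 127 (-5.01 ± 0.34, adjusted p = 0.00229). Tnnc1, a troponin of heart muscle, changed by -4.92 ± 0.40 (adjusted p = 0.00297), and Dlk1 was 1.93 against 913 CPM (adjusted p = 0.00322). Epithelial genes fell in 5 of 11, with Krt5 at 0.612 against 705 CPM (adjusted p = 0.00322). Endoderm genes depended on replicate 3: 1 of 20 fell and 0 rose with it, 15 of 19 fell and 2 rose without it, and in replicate 3 alone 5 were more than 2-fold higher and 6 lower. Without replicate 3, the GFP-positive libraries all belong to the second sequencing project and the day-15 library to the first, so group and project cannot be told apart. For each of the genes named here all 3 GFP-positive libraries lay on the same side of the day-15 library, a separation that chance gives to 50% of genes in this design.

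Further lists were examined against day-15 cells, where 46.3% of all genes tested were called. All 19 G2-M genes of dividing cells rose, such as the checkpoint kinase Bub1 (1.44 ± 0.16, adjusted p = 0.00472), and 21 of 30 oxidative phosphorylation genes rose, such as Cox5a (1.71 ± 0.18, adjusted p = 0.00426). Of 9 DNA methylation genes 8 rose, led by the demethylating enzyme Tet1 at 846 against 32 CPM (adjusted p = 0.00285), and 1, Tet3, fell by 1.88 on the log2 scale. AMPK pathway genes rose in 9 of 26 and fell in 2, with Sirt1 at 223 against 28.5 CPM (2.97 ± 0.32, adjusted p = 0.00429) and the stress sensor Sesn2 up by 1.33. Camera called the naive list (adjusted p = 5.6e-18) and the mesenchyme list (1.2e-20) among 13 lists, and not the AMPK list (0.131). All 13 calls were lost with an estimated correlation (adjusted p = 0.36 for both of these lists and 0.533 for the G2-M list). At 2 residual degrees of freedom that form can hardly call a list, so the losses decide nothing. In the edgeR quasi-likelihood test 3430 genes of 14857 rose and 3453 fell. Named by the rule, Cyp2b23 was at least 187-fold higher, Trim43b at least 29.8-fold and Rhox13 at least 29.5-fold, each with 0 reads in day-15 cells. Lower were Lum (1 read in the GFP-positive cells, ratio 10800, interval 1930 to 426000), Krt15 (ratio 8140, 1460 to 322000) and Mgp (0 reads, at least 643-fold). Lower too were Col3a1 (2.62 against 10200 CPM, adjusted p = 0.0131) and Lox, a collagen cross-linking enzyme (0.133 against 396, adjusted p = 0.00165). The Col3a1 mean of the GFP-positive cells rests on replicate 3 (7.27 CPM), with a mean of 0.0 in replicates 1 and 2. In replicate 3 alone, the 1 replicate of the same sequencing project as the day-15 library, 5129 of the 6883 called genes differed by at least 2-fold, but replicate 3 helped to make these calls, so this is no independent check on the project. Without replicate 1 the counts were 2079 up, without replicate 2 they were 1311 up and 1552 down. Without replicate 1 or 2, 11 or 4 oxidative phosphorylation genes, 5 or 4 methylation genes and 5 or 5 AMPK pathway genes rose. Without replicate 2, 10 G2-M genes rose and 13 imprinted genes fell, and without replicate 3, 11 of 11 epithelial and 6 AMPK pathway genes fell.

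AICAR GFP-positive cells were tested against undifferentiated cells, the state from which the culture began. Part of the epiblast genes were higher in the GFP-positive cells, and Nanog was lower. Nanog fell, at 235 ± 33 (SD, n = 3) against 599 CPM (log2 -1.35 ± 0.19 SE, adjusted p = 0.0416), the only naive gene of 18 called. Fbxo15 was -1.59 ± 0.31 (adjusted p = 0.0522) and Klf5 -0.93 (adjusted p = 0.0526). Epiblast genes rose in 5 of 15 and fell in 1: Otx2 was 106 ± 11.6 against 2.58 CPM (5.36 ± 0.28, adjusted p = 0.00929). Fgf5 had 1 read in undifferentiated cells (ratio 77.5, interval 13.8 to 3070, adjusted p = 0.0248). Fgf15 rose by 4.64 ± 0.53 (adjusted p = 0.0415), and Lefty2, an inhibitor of Nodal signals, was 58 against 314 CPM (-2.44 ± 0.12, adjusted p = 0.00929). Of the MEK-ERK response genes 3 of 16 rose and 0 fell, Dusp4 at 43.3 against 10.6 CPM (2.02 ± 0.25, adjusted p = 0.0416) and Ccnd1, cyclin D1, at 113 against 27.1 (2.06 ± 0.35, adjusted p = 0.0484). Oxidative phosphorylation genes fell in 4 of 30, such as Uqcrc1 at 241 against 537 CPM (-1.16 ± 0.14, adjusted p = 0.0416). The 2-cell-like genes fell in 2 of 7, such as Zscan4c (1.62 against 80.7 CPM, adjusted p = 0.0416, with reads shared between copies). In the p53 target list 1 of 16 rose, Trp53inp1 at 107 against 47.5 CPM (1.17 ± 0.16, adjusted p = 0.0416). No endoderm gene of 20 passed the test, with Cubn at 284 ± 319 against 1.77 CPM (7.31 ± 2.05, adjusted p = 0.0925) and Dab2 at 6.94 ± 2.57 (adjusted p = 0.154). Replicate 3 alone held 18 of the 20 at more than 2-fold above the undifferentiated library.

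Adjusted over the list alone, 9 naive genes fell, 8 epiblast genes rose and 2 fell, 16 oxidative phosphorylation genes fell, 6 of the 2-cell-like genes fell, 4 MEK-ERK genes rose, 9 p53 targets rose and 1 fell, and 0 endoderm genes were called. Camera called the naive (adjusted p = 1.3e-04), epiblast (0.00227), 2-cell-like (3.8e-05), oxidative phosphorylation (8.3e-07), endoderm (0.00144), MEK-ERK (0.00561), p53 (0.00227) and purine synthesis (0.00615) lists. None was kept with an estimated correlation (adjusted p = 0.679 for the naive, epiblast, 2-cell-like and purine lists, 0.728 for the oxidative phosphorylation and MEK-ERK lists, 0.782 for p53 and 0.814 for endoderm with an estimated correlation). The fit had 2 residual degrees of freedom, too few for that form to decide. Named by the rule, Ccnd2 had 0 reads in undifferentiated cells and was at least 53.4-fold higher. Myl9 and Wt1 had 1 read there (ratios 60.3, interval 10.7 to 2390, and 58.2, interval 10.4 to 2300), and Arhgef28 stood at 62.7 against 1.29 CPM (adjusted p = 0.00929). Lower were Cdx1, a target of Wnt signals, at 0.575 against 47.2 CPM (-6.33 ± 0.30, adjusted p = 0.00929). So were Pmel, Accsl and Calcoco2 (-5.85, -5.80 and -5.81, adjusted p = 0.0177, 0.0177 and 0.0232), Aox3 (-5.74 ± 0.98, adjusted p = 0.0484) and Arhgdib (-5.61). The edgeR quasi-likelihood test called 331 genes higher and 358 lower of 13640. In replicate 3, the 1 replicate of the same sequencing project, 545 of these 689 differed by at least 2-fold, which is no independent check on the project since replicate 3 helped to make the calls. The counts rested on single replicates: they were 13 and 37 without replicate 1, 0 and 0 without replicate 2 (3998 genes had unadjusted p under 0.05 with all 3, and DESeq2 called 1054 and 1040), and 2037 and 2121 without replicate 3. The epiblast genes called higher were 1 without replicate 1, 0 without replicate 2 and 8 without replicate 3, and the oxidative phosphorylation genes called lower 0, 0 and 16. Without replicate 3, 11 naive and 4 of the 2-cell-like genes were called lower and 7 MEK-ERK, 9 p53 and 10 of 17 endoderm genes higher. Without replicate 3, the GFP-positive libraries all belong to the second sequencing project and the undifferentiated library to the first. Group and project cannot then be told apart. With all 3 replicates and the same spread for all genes, 3% of simulated 2-fold and 51% of 4-fold changes were recovered.

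AICAR GFP-positive and GFP-negative cells of the same culture type were compared to show what the reporter separates. No gene passed the edgeR quasi-likelihood test, so values are given without a call. Naive factors were higher in the GFP-positive cells: Zfp42 was 587 ± 119 (SD, n = 3) against 61.3 CPM (log2 3.26 ± 0.32 SE, adjusted p = 0.138). Nanog was 242 ± 34.4 against 37.2 (2.70 ± 0.25, adjusted p = 0.138). Genes of G2-M such as Top2a, the DNA topoisomerase of dividing cells, were 1180 against 592 CPM (1.00 ± 0.16, adjusted p = 0.138). Matrix genes lay lower, Col5a1 at 18.5 against 64.9 CPM (-1.82 ± 0.26, adjusted p = 0.138) and the matrix protease Mmp2 at 11.8 against 41.9 (-1.83 ± 0.27). So did the contractile regulators Cnn1 and Cald1 at 1.36 against 14.7 and 42.1 against 306 (adjusted p = 0.15 and 0.154). Fibronectin, Fn1, was 1960 against 1160 (adjusted p = 0.139). Adjusted over the list alone, 14 of 18 naive genes were higher and 1 lower, 16 of 19 G2-M genes higher, 8 of 22 mesenchyme genes lower and 1 higher, and 0 of 12 smooth muscle genes called.

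Camera called the naive (adjusted p = 1.9e-20), G2-M (2.4e-10), mesenchyme (3.5e-08) and smooth muscle (1.2e-06) lists among 10 lists. None of these 4 was kept (adjusted p = 0.561 for each with an estimated correlation). The fit had 2 residual degrees of freedom, too few for the form with an estimated correlation to decide. Of 13821 genes 0 were called, 3022 had unadjusted p under 0.05, DESeq2 called 629 higher and 581 lower, limma called 0, and the fit of all 19 libraries 1815 and 1733. In replicate 3 alone, the replicate of the same sequencing project as the GFP-negative library, 16 of 18 naive genes were more than 2-fold higher. There 15 of 22 mesenchyme and 8 of 12 smooth muscle genes were more than 2-fold lower, and of 20 endoderm genes 6 were higher and 9 lower. The result rested on replicate 3: without it 1744 genes were higher and 2209 lower, with 14 naive and 17 G2-M genes higher and 16 mesenchyme and 11 smooth muscle genes lower. Without replicate 3, the GFP-positive libraries all belong to the second sequencing project and the GFP-negative library to the first. Group and project cannot then be told apart. With all 3 replicates 0% of simulated 2-fold and 30% of 4-fold changes were recovered.

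Colony lines were tested against AICAR GFP-positive cells to show how lines expanded in LIF with both inhibitors differed from these cells. Of 12225 genes tested 57.9% were called, 3369 higher and 3704 lower, and list counts are to be read against that share. Naive genes rose in 13 of 17 and fell in 2. Nanog was 502 ± 43.5 (SD, n = 8) against 225 ± 32.8 CPM (SD, n = 3; log2 1.16 ± 0.10 SE, adjusted p = 7.2e-07). Klf5 rose by 1.03 ± 0.12 (adjusted p = 6.1e-06) and Klf4 fell, 149 ± 16.6 against 290 ± 27.8 CPM (-0.96 ± 0.09, adjusted p = 1.6e-06). Epiblast genes fell in 11 of 15 and rose in 2. Otx2, which drives the exit to the epiblast state, was 2.1 ± 0.559 against 102 ± 11.7 CPM (-5.60 ± 0.14, adjusted p = 1.5e-11). The growth factor Fgf15 was 0.6 against 19.5 (-5 ± 0.23, adjusted p = 2.5e-09) and Dnmt3a 59 against 250 (-2.08 ± 0.12, adjusted p = 2.1e-08). Lefty2 rose (1.94 ± 0.14, adjusted p = 9.6e-08). Of 16 MEK-ERK response genes 10 fell and 0 rose, led by the phosphatase Dusp4 (-4.30 ± 0.14, adjusted p = 1.5e-10) and Ccnd1 (-1.79 ± 0.17, adjusted p = 1.2e-06). Endoderm genes fell in 15 of 16, such as Dab2, an endocytic adaptor, at 2.4 against 115 ± 147 CPM (-5.56 ± 0.70, adjusted p = 1.6e-05). Of this list, 11 members were picked as far higher in the GFP-negative library than in AICAR GFP-positive replicates 1 and 2. In replicate 3 their median lay 0.228 of the way to the GFP-negative level. Dab2, 1 of them, was 285.46 CPM in replicate 3 against 30.28 and 30.01 in replicates 1 and 2. That is above its GFP-negative level of 237 CPM. The 2-cell-like genes rose in 6 of 6, and Zscan4c stood at 84.1 ± 56.1 against 1.55 CPM (5.83 ± 0.84, with reads shared between copies). General pluripotency genes split, 9 of 18 up and 6 down, with Gdf3 up by 1.37 ± 0.13 (adjusted p = 1.0e-06). Epcam, Utf1 and Sox2 fell, with log2 values of -1.72 ± 0.16, -1 ± 0.10 and -0.76 ± 0.09 (adjusted p = 1.1e-06, 1.7e-06 and 1.1e-05). Streak genes rose in 3 of 5 and fell in 1, with T up by 2.2 ± 0.57 and Foxa2, a factor of definitive endoderm, at -3.22 ± 0.79 (adjusted p = 0.00305).

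Between colony lines and AICAR GFP-positive cells, purine synthesis genes rose in 11 of 17 and fell in 2. Atic, the enzyme that acts on the phosphorylated form of AICAR, stood at 358 ± 19.9 against 218 ± 6.99 CPM (0.71 ± 0.07, adjusted p = 1.2e-06) and Gart rose by 0.48 ± 0.06. Oxidative phosphorylation genes rose in 14 of 30 and fell in 1, with Uqcrc1 of complex III at 435 against 230 CPM (0.92 ± 0.09, adjusted p = 2.6e-06). In the p53 target list 11 of 15 fell and 1 rose (12 and 1 adjusted over the list alone), with Btg2, a brake on proliferation, at 5.48 against 23.4 CPM (-2.10 ± 0.21, adjusted p = 1.9e-06). AMPK pathway genes fell in 7 of 25 and rose in 3. The transcription factors Foxo3 and Foxo1 were 26.6 against 88.7 (-1.74 ± 0.17, adjusted p = 1.8e-06) and 15 against 35.2 CPM (-1.23 ± 0.10, adjusted p = 2.4e-07). The kinase Ulk1 was 209 against 116 (0.84 ± 0.07, adjusted p = 5.0e-07). Imprinted genes fell in 13 of 26 and rose in 3. Magel2 and Ndn fell (-4.59 ± 0.43 and -1.79 ± 0.17, adjusted p = 1.1e-06 and 1.2e-06) and Plagl1 was 64.7 against 6.17 CPM (3.52 ± 0.47, adjusted p = 2.7e-05). Camera called the epiblast list (adjusted p = 4.8e-07) and kept it (adjusted p = 0.00536 with an estimated correlation). The calls of the MEK-ERK (0.00116), endoderm (0.00411), naive (0.00837), 2-cell-like (0.0104), purine (0.0166), p53 (0.0166), oxidative phosphorylation (0.0236) and streak (0.031) lists were lost (adjusted p = 0.207, 0.599, 0.264, 0.582, 0.264, 0.582, 0.615 and 0.357 with an estimated correlation). The AMPK (0.311), imprinted (0.235) and general pluripotency (0.842) lists were not called. Except where given, the counts adjusted over the list alone equalled those over all genes. In the first sequencing project alone, with replicate 3 as the only GFP-positive library, 13 naive genes rose and 1 fell, and 11 epiblast and 18 of 19 endoderm genes fell. There 11 purine and 14 oxidative phosphorylation genes rose and 6 p53 targets fell. Replicate 3 helped to make the calls over all libraries and held more endoderm reads than replicates 1 and 2. Its counts are therefore no independent check. Without replicate 3, 10 endoderm genes fell and 1 rose, and 6 imprinted genes rose.

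Camera called none of the lists not yet described for these groups. Over all genes tested 57.9% were called, so a list with a share of calls near or below this shows no response of its own. Mesenchyme genes rose in 2 of 16 and fell in 7 (3 and 8 adjusted over the list alone), and smooth muscle genes fell in 2 of 9. Cardiac genes rose in 2 of 5. Neural genes rose in 1 of 9 and fell in 5 (2 and 5 adjusted over the list alone). Trophoblast genes rose in 2 of 4, and endothelial and blood genes fell in 4 of 6. Epithelial genes rose in 2 of 8 and fell in 2, germline genes rose in 2 of 15 and fell in 8, and DNA methylation enzymes rose in 2 of 9 and fell in 5. Wnt response genes rose in 2 of 9 and fell in 6 and LIF-STAT3 response genes rose in 5 of 10 and fell in 4. Glycolysis genes rose in 3 of 21 and fell in 3, and sterol and fatty acid synthesis genes rose in 1 of 23 and fell in 11. G2-M genes rose in 6 of 19 and fell in 5 and stress genes rose in 7 of 16 and fell in 5. The glycolysis, G2-M and stress lists had medians above 0 and means below 0. Without AICAR GFP-positive replicate 3, 12 glycolysis genes and 4 trophoblast genes rose, and 5 sterol, 2 endothelial and 2 stress genes fell. Epithelial genes that fell were 4 of 7 without colony line 5, 6 of 8 without AICAR GFP-positive replicate 1 and 5 of 8 without replicate 2, and 5 glycolysis genes fell without colony line 9.

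**Figure D3:**
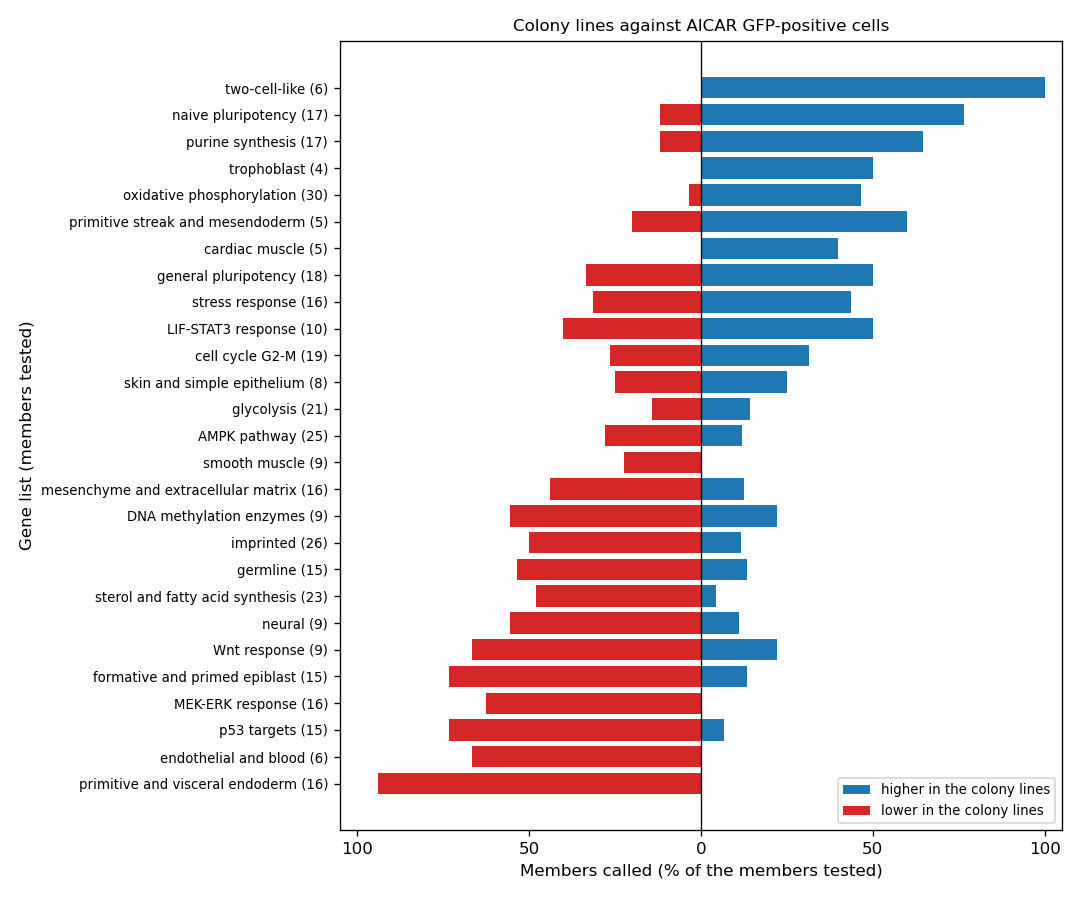
Percent of the tested members of each of the 27 gene lists that the edgeR quasi-likelihood test called higher (blue, to the right) or lower (red, to the left) in colony lines than in AICAR GFP-positive cells, with the number tested after each name. All 6 of the 2-cell-like genes are higher, 13 of 17 naive genes are higher and 2 lower, and 15 of 16 endoderm genes and 11 of 15 epiblast genes are lower. Over all genes tested 57.9% were called.

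Among the genes with the largest rise in colony lines over AICAR GFP-positive cells was Aox3, an aldehyde oxidase (29 ± 10.3 against 0.263 ± 0.237 CPM, log2 6.70 ± 0.51, adjusted p = 2.0e-07). Another was Pmel, a pigment granule protein (61.9 ± 9.73 against 1.11, 5.84 ± 0.24, adjusted p = 1.0e-09). Calcoco2, an autophagy receptor, Ido2 and Cdx1 (27 ± 5.48 against 0.55 CPM, 5.57 ± 0.27, adjusted p = 4.3e-09) followed, with Zscan4a, Zscan4b, Zscan4c and Zscan4f between 5.55 and 5.95. Among the largest falls were the endoderm genes Cubn (0.93 ± 0.753 against 270 ± 302 CPM, -8.15 ± 0.61, adjusted p = 1.6e-07) and Amn, its partner (0.151 against 23.4 ± 28.8, -7.14 ± 0.76). Falls followed in the water channel Aqp8 (-6.86 ± 0.78), Nostrin (-6.58 ± 0.82), Ctsh, Sox7 (-5.79 ± 0.91) and Pth1r. Apoa1, an apolipoprotein, and Pax8 rested on 2 and 3 reads in the colony lines (ratios 154, interval 42.2 to 1280, and 72.3, interval 24.3 to 355). The large SDs come from replicate 3, where Cubn was 619.29 CPM against 101.07 and 91.13 in replicates 1 and 2. In all, 3369 genes of 12225 rose and 3704 fell in the edgeR quasi-likelihood test, 868 and 1565 by at least 2-fold. Every library of one group lay above every library of the other for 5277 of the called genes. Over all genes tested this held for 5318, or 43.5%, where chance gives 1.2%. In the first sequencing project alone 2748 rose and 3130 fell, 4759 of them shared with the same direction, and 89 of the calls over all libraries changed sign. Replicate 3, the only GFP-positive library of that fit, helped to make the calls over all libraries, as did the same colony lines. The shared calls are therefore no independent check on the project. Simulated 2-fold and 4-fold changes were recovered at 93% and 97%.

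Sorted lines were tested against AICAR GFP-positive cells, the cells they were grown from by another route. Of all genes tested 36.7% were called. Naive genes rose in 7 of 18 and fell in 1, with Nanog at 552 against 231 CPM (log2 1.25 ± 0.13 SE, adjusted p = 0.00207, n = 2 and 3) and Klf4 lower (-0.95 ± 0.11, adjusted p = 0.00258). Epiblast genes fell in 7 of 15 and rose in 1 (8 and 2 adjusted over the list alone), with Otx2 at 1.9 against 105 CPM (-5.75 ± 0.23, adjusted p = 2.0e-04). Fgf15 and Dnmt3a were lower (-4.03 ± 0.37 and -1.82 ± 0.18) and Lefty2 higher (1.86 ± 0.08, adjusted p = 3.4e-04). Endoderm genes fell in 9 of 17 (12 adjusted over the list alone). The 2-cell-like genes rose in 6 of 6, with Zscan4f at 138 ± 18.2 against 1.59 CPM (6.51 ± 0.66, adjusted p = 0.00205, reads shared between copies). Purine genes rose in 11 of 17 and fell in 2, the salvage enzymes Aprt (0.83 ± 0.08, adjusted p = 0.00204) and Hprt (0.82 ± 0.10, adjusted p = 0.00264) ahead of Atic (0.73 ± 0.08, adjusted p = 0.00245). Camera called these lists (adjusted p = 0.00137 for naive, endoderm and purine, 1.5e-04 for epiblast and 3.1e-06 for 2-cell-like). None was kept (adjusted p = 0.51, 0.671, 0.429, 0.429 and 0.506 with an estimated correlation). The fit had 3 residual degrees of freedom, too few for the form with an estimated correlation to decide. Of the named genes, Calcoco2 was 117 ± 3.92 against 1.4 CPM (6.29 ± 0.32, adjusted p = 4.4e-04). Crygd, an eye lens protein, had 1 read in the GFP-positive cells (ratio 187, interval 32.3 to 7480, adjusted p = 0.00245). Grin2a had 0 reads in the sorted lines (at least 31.5-fold lower), and Gata6, a driver of endoderm, and Ccnd2 had 3 and 2 reads (ratios 97.1, interval 33.1 to 472, and 153, interval 42.2 to 1260). The Gata6 ratio leans on AICAR GFP-positive replicate 3, at 69.7 CPM against a mean of 8.37 in replicates 1 and 2. Cubn (-7.22 ± 1.4, adjusted p = 0.0105) and Cyp26a1, which breaks down retinoic acid (-5.97 ± 1.77, adjusted p = 0.0399), fell too. For both, the AICAR GFP-positive replicates differed widely, at 281 ± 316 and 31.7 ± 40.8 CPM (SD, n = 3). In the edgeR quasi-likelihood test 2210 genes of 12593 rose and 2407 fell, and in the first project alone 3842 and 4026. There replicate 3 is the only AICAR GFP-positive library, so the spread comes from the 2 sorted lines alone. Replicate 3 also held more endoderm reads than replicates 1 and 2, so that fit is no independent check on the fall of endoderm genes. The counts rest on both sorted lines: without sorted line 1 they were 171 and 150, without sorted line 2 they were 208 and 179. Without sorted line 1 or 2, 1 naive gene rose, 5 or 4 epiblast genes and 0 endoderm genes fell, and 2 of the 2-cell-like and 0 or 1 purine genes rose. Without AICAR GFP-positive replicate 3, 11 naive genes rose.

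Colony and sorted lines were compared to show whether picking colonies or sorting cells gave different lines. No gene passed the edgeR quasi-likelihood test, and Nanog and Zfp42 lay close: Nanog was 515 ± 42.4 (SD, n = 8) and 545 ± 12.6 CPM (SD, n = 2), Zfp42 563 ± 84.5 and 506 ± 2.51. T, at few reads, was 2.8 ± 0.699 and 1.44 ± 0.119 CPM without overlap (adjusted p = 0.52). Of 30 oxidative phosphorylation genes, among them Atp5g1 (log2 -0.38 ± 0.14 SE, adjusted p = 0.52) and Tfam, which maintains mitochondrial DNA (0.22 ± 0.09, adjusted p = 0.524), 0 passed over all genes and 0 adjusted over the list alone. The same held for 21 glycolysis genes, with the glucose transporter Slc2a1 at -0.30 ± 0.15 and Pfkm at 0.22 ± 0.11 (adjusted p = 0.551 for both). Camera called both lists lower in colony lines (adjusted p = 0.00278 and 0.0218), and neither was kept (adjusted p = 0.752 for both with an estimated correlation). Of 11870 genes tested 0 passed, 1092 had unadjusted p under 0.05, DESeq2 called 1 higher and 1 lower and limma 1 higher and 0 lower. Libraries of the 2 groups did not overlap for 1114 genes, 9.4% of those tested, where chance gives 4.4%, so small differences below the threshold are not excluded, and 84% of simulated 2-fold changes were recovered. All libraries of this comparison belong to the first sequencing project.

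Colony lines were tested against undifferentiated cells to show how far the lines lay from the starting cells. Few genes passed the test. Lower were the ERK phosphatase Dusp4 at 2.03 ± 0.433 (SD, n = 8) against 9.74 CPM (log2 -2.25 ± 0.28 SE, adjusted p = 0.036) and the proline synthesis enzyme Aldh18a1 at 14.9 ± 2.24 against 37.8 (-1.34 ± 0.18, adjusted p = 0.0406). The antiproliferative gene Btg1 was lower too, at 21.7 ± 1.82 against 40.6 CPM (-0.90 ± 0.13, adjusted p = 0.0432). All 8 lines lay on the same side of the undifferentiated library for each of these genes. They did so for 5500 genes, 44.7% of those tested, where chance gives 22.2%, so differences below the threshold are not excluded. No general pluripotency gene of 18 and no DNA methylation gene of 9 passed over all genes, against 6 and 3 higher adjusted over the list alone. L1td1 was 982 against 694 CPM (0.50 ± 0.11, adjusted p = 0.102). The RNA-binding protein Lin28a was at 0.82 ± 0.19 (adjusted p = 0.103) and the methylation cofactor Dnmt3l 318 against 184 CPM (0.79 ± 0.14, adjusted p = 0.0737). No glycolysis gene of 21 and no oxidative phosphorylation gene of 30 passed, against 1 lower in each adjusted over the list alone. Among them were the glucose transporter Slc2a3 at 516 against 753 CPM (-0.54 ± 0.13, adjusted p = 0.12) and Cox6a1 at -0.47 ± 0.12 (adjusted p = 0.122). Camera called the general pluripotency and methylation lists higher (adjusted p = 0.0179 for both) and the glycolysis (7.1e-04) and oxidative phosphorylation (3.1e-05) lists lower, and none was kept (adjusted p = 0.538, 0.538, 0.56 and 0.56 with an estimated correlation). Of 12314 genes 1 was higher and 3 lower in the edgeR quasi-likelihood test, with 2385 at unadjusted p under 0.05, and DESeq2 called 286 and 94. Without colony line 7 the counts were 4 and 12, and 63% of simulated 2-fold and 89% of 4-fold changes were recovered.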

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

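Of the tests in this part only the count of other splits was chosen before its result was seen, and all the others were chosen after.

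The result compared most often here, the 7073 genes called between colony lines and AICAR GFP-positive cells, was set against other groupings of the same 11 libraries. Of 100 splits drawn from 165 possible ones, 1, the real one, called as many genes, and the highest of the others called 36. The split with 36 set AICAR GFP-positive replicates 2 and 3 and colony line 7 against the rest. In 5 other drawn splits both libraries of the second sequencing project were on the smaller side, and these splits called at most 2 genes. Every split but the real one puts libraries of both groups on the same side, which widens the spread and lowers the calls. The counts therefore cannot exclude chance, and they say nothing about the sequencing project.

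In the 8 colony lines, 98 values (key, named, list and Y-linked genes and chromosome medians) were searched for a library far from the other lines, and 10 were found. Chance marks about 1 in 20 groups, so about 5 percent of such values are found without any cause. Zfp42 was 367 CPM in colony line 7 against 550 to 645 in the other lines. The Y-linked genes Ddx3y and Eif2s3y stood at 0 and 0.52 CPM in colony line 7 against 70.4 to 119 and 67.9 to 124. The chromosome 8 median of colony line 7 was -0.555 on the log2 scale, far from the other lines. Kdm5d, also Y-linked, was 15.7 CPM in colony line 4 against 0 to 7.41 elsewhere. Aldoc, a glycolytic aldolase, was 22.1 CPM in colony line 9 against 6.23 to 13.5. Colony line 9 also had the lowest medians for chromosomes 4 (-0.026), 9 (-0.045), 16 (-0.055) and 18 (-0.059), all of them small.

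Colony line 7 had 3 reads in 4 Y-linked genes where 1424 would match the other lines, and its chromosome 8 genes lay low while its other chromosomes lay between -0.016 and 0.033. Cells with 2 active X chromosomes in place of XY cells are argued against by the X-linked genes, whose median difference was 0.0. Loss of 1 of 2 copies of chromosome 8 in every cell is argued against by the median of -0.555, which lies above the -1 that such a loss gives. A lower dose of the whole chromosome remains a candidate explanation: the 4 equal parts of the chromosome ordered by position (assembly GRCm38.p6) had medians from -0.6 to -0.51, near the -0.58 of 2 copies against 3, and a loss in part of the cells is not excluded. The design names no biological difference for this line, so no biological explanation was tested beyond these chromosome changes, and Zfp42 lies on chromosome 8.

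AICAR GFP-positive replicate 3 held more endoderm, mesenchyme and smooth muscle reads than replicates 1 and 2, with Col4a1 at 4190 CPM against a mean of 288 and Lama1 at 3040 against 185. A share of cells like those of the GFP-negative library, where Col4a1 is 17400 and Lama1 15000 CPM, may account for most of it: over 28 genes of these lists replicate 3 lay 0.229 of the way to the GFP-negative level (95% interval 0.208 to 0.261), and over 9 naive genes 0.311 (0.247 to 0.37), although the GFP gate would remove such cells. It cannot account for Cubn (619 against 160 CPM in the GFP-negative library), Amn (56.6 against 24.9), Apoa1 (19.2 against 2.69) and Apob (27.6 against 4.27). These 4 of the 16 raised endoderm genes, 25 percent, lay more than 2-fold above both the GFP-negative library and replicates 1 and 2. The same held for 0.6 percent of 10035 expressed genes. The 16 were picked for lying more than 2-fold above replicates 1 and 2, the expressed genes were not, so the shares cannot be compared. Of the 28 genes, 12 also stood at 5 CPM or more in colony lines, and no gene is in more than 1 of these lists. The difference between sequencing projects cannot be told apart from that between the replicates, since 0 libraries of another group are in the second project.

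The unfractionated AICAR library lay above both of its fractions in mesenchyme and smooth muscle genes, with Col1a1 at 3850 CPM against 154 in GFP-negative and at most 40.4 in GFP-positive cells. A mixture of the cells of both fractions is argued against, since 75 percent of 32 genes of these lists stood more than 2-fold above every library of both fractions. A general difference in library composition is argued against too, since this held for 5.0 percent of 11229 expressed genes and for 0 of 17 naive genes. Cells outside both gates, or different cultures behind the libraries, remain open and were not tested.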

How the results depend on the processing

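The alternatives chosen after the data were seen were the first sequencing project only, colony lines 4 and 5 left out and colony line 7 left out. The main results compared here are counts of genes or lists. Of their alternative values from the planned choices, 138 equalled the reported count or stayed within 1.5 times of it. Beyond that range 25 were larger and 27 smaller, and 2 counts without a test moved out of it. Depth limits what could be seen: 3 reads, the floor of a zero count, are 0.211 to 0.52 CPM in a library. The causes of the shifts below were not tested, except that fits without a replicate have fewer samples.

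DESeq2 called 1054 genes higher and 1040 lower in AICAR GFP-positive than in undifferentiated cells, 629 and 581 against GFP-negative cells, 1 and 1 between colony and sorted lines, and 286 and 94 between colony lines and undifferentiated cells. One fit of all 19 libraries called 2131 and 2173 against undifferentiated cells, 1815 and 1733 against GFP-negative cells, and 0 and 1 for colony lines against undifferentiated cells. For the same colony comparison all 10 lines as 1 group gave 2 and 5, median-of-ratios factors 0 higher, and leaving out colony lines 4 and 5 gave 0 higher. limma on log2 RPKM called 28 higher and 21 lower in AICAR GFP-positive than in undifferentiated cells, 1 higher in colony than in sorted lines, and 2 and 6 between colony lines and undifferentiated cells. Its scale moved the median gene by -0.146 and -0.155 for colony and sorted lines against AICAR GFP-positive cells and by 0.161 for these against undifferentiated cells. Of its calls for colony lines against AICAR GFP-positive cells 2358 were higher and 4606 lower. Without the expression filter 523 genes were higher in AICAR GFP-positive than in undifferentiated cells and 2 lower than in GFP-negative cells. In the first sequencing project only, 3842 were higher and 4026 lower in sorted lines than in AICAR GFP-positive cells. That fit has replicate 3 as its only AICAR GFP-positive library. With replicate number as a block for replicates 1 and 2 of both groups 3347 were higher, against 3191 in the same 4 libraries without it, and the numbers are not shown to pair samples. With log2 of RPKM plus 0.1 the day-2 libraries differed by more than 2-fold in 35 genes higher and 4 lower.

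Camera with an estimated correlation called 1 list between colony lines and AICAR GFP-positive cells and 0 in each of the other 6 tested comparisons. It could hardly call any in the fits with 2 or 3 residual degrees of freedom. These were AICAR GFP-positive cells against single libraries and sorted lines. fry called 22 lists between colony lines and AICAR GFP-positive cells, 9 between sorted lines and AICAR GFP-positive cells, 13 between AICAR GFP-positive and day-15 cells, 1 between colony lines and undifferentiated cells, and 0 for colony against sorted lines and for AICAR GFP-positive against undifferentiated and GFP-negative cells.

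Small differences changed sign. Zfp42 between colony lines and AICAR GFP-positive cells, 0.01 as reported, was -0.02 with all 10 lines and -0.14 with limma, and -0.15 to 0.14 over single replicates left out, with -0.15 without AICAR GFP-positive replicate 3. Zfp42 between sorted lines and AICAR GFP-positive cells, -0.13 as reported, was 0.26 in the first project only. Esrrb between AICAR GFP-positive and undifferentiated cells, -0.08 as reported, was 0.24 with limma and -0.23 to 0.06 over single replicates left out, 0.06 without AICAR GFP-positive replicate 3. Esrrb between sorted lines and AICAR GFP-positive cells, 0.16 as reported, was -0.06 with limma, and between colony and sorted lines, 0.06 as reported, -0.01 to 0.15, -0.01 without sorted line 2. Klf4 between colony and sorted lines, -0.01 as reported, was 0 without the filter and 0.03 without sorted line 1.

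Leaving out 1 replicate at a time gave 1311 to 4500 genes higher and 1552 to 4913 lower in AICAR GFP-positive than in day-15 cells. Against undifferentiated cells it gave 0 to 2037 higher and 0 to 2121 lower, both 0 without replicate 2, where 3998 genes had unadjusted p under 0.05 over all replicates by edgeR. Against GFP-negative cells it gave 0 to 1744 and 0 to 2209, both ends high only without replicate 3. For sorted lines against AICAR GFP-positive cells it gave 171 to 3191 higher and 150 to 3323 lower, for colony lines against AICAR GFP-positive cells 3011 to 3440 and 3419 to 3700. Colony lines against undifferentiated cells gave 4 and 12 without colony line 7. Where this leaves 1 library on a side, the lone sample is assumed to vary like the other group. Without replicate 3, the AICAR GFP-positive libraries all belong to the second sequencing project and those they are compared with to the first. Group and project cannot then be told apart.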

Other observations

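The values in this part were picked after they were seen, and no test was run on them. Beside matrix genes, a few others stood far above both fractions in the unfractionated AICAR library. Ptgs2, a prostaglandin synthase, was 191 CPM against 3.64 in GFP-negative cells, at most 2.31 in GFP-positive cells and 69.4 at day 15 without AICAR. Inhba, an activin subunit, was 111 CPM, and the collagen cross-linking enzyme Lox 161 CPM against 3.32 in GFP-negative and at most 0.22 in GFP-positive cells. By list, 4 of 6 trophoblast, 5 of 9 epithelial and 6 of 16 p53 target genes lay more than 2-fold above every library of both fractions, and 0 of 16 endoderm and 0 of 25 AMPK pathway genes did.

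Zscan4c, a 2-cell-like gene with reads shared between near-identical copies, was highest in the day-2 SSEA1-negative GFP-negative cells, at 686 CPM against 76 in undifferentiated cells, and averaged 1.55 CPM in AICAR GFP-positive cells and 84.1 in colony lines. Plagl1, an imprinted zinc finger gene that restrains growth, was 694 CPM at day 15 without AICAR, 64.7 in colony lines and 6.17 in AICAR GFP-positive cells. Among colony lines, line 5 held the most endoderm reads, with Col4a1 at 697.39 CPM against 20.77 in line 10, and line 4 the most Col1a1 reads, 76.88 CPM.

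Chromosome medians also differed between AICAR GFP-positive replicates. The median log2 difference of chromosome 8 genes from the mean of the other replicates was 0.224 in replicate 1, 0.012 in replicate 2 and -0.247 in replicate 3. Other chromosomes moved too: chromosome 6 was at 0.151, -0.203 and 0.066, chromosome 19 at -0.056, -0.144 and 0.192, and chromosome 14 at 0.122 in replicate 1. The Y-linked gene Ddx3y was 16.4 and 26.2 CPM in replicates 1 and 2, 46.2 in replicate 3 and 34.5 in undifferentiated cells. Replicates 1 and 2 belong to the second sequencing project. In sorted lines 1 and 2 chromosome 11 genes had a median log2 difference of 0.1 and 0.12 from the median of the colony lines. Single colony lines, each set against the other colony lines, lay between -0.023 (line 4) and 0.024 (line 10) there.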
